A study of Cladosporium europaeum with 50 samples.

How the data were processed

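Mycelium of Cladosporium europaeum strain F32 was sampled in 10 groups of 5 replicates, a control and 4 PCB congeners at 24 h and at 96 h. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a polyA method. The aligner, the read counter, the genome build, the gene annotation and the program of the differential test are not given in the sources used here. The gene identifiers join a contig name and a gene number, and no genome was used, so positions beyond these identifiers are not reported.

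The authors deposited tables of comparisons, and no values per sample were used here. In the deposited tables each row is a gene in a comparison, with a log2 fold change and its standard error on the log2 scale, a test statistic (a score with no fixed range), an unadjusted p-value and an adjusted p-value, and a mean normalized count, a signal that is never negative, per the file headers. A shorter copy of the deposited tables, rounded to 2 decimals, adds the annotation, with 887 rows for 833 gene and comparison combinations. It was within 0.005 of the longer table in log2 fold change. The score deposited by the authors equals the log2 fold change over its standard error and the deposited p-value is the two-sided normal p of that score, as checked on all 1102 rows. The mean normalized count was the same for a gene in every comparison. Rows of a congener against control had an adjusted p under 0.05 and an absolute log2 fold change of at least 1, and the 1 row of the direct comparison of PCB180 with PCB153 had 0.86 in the authors' deposited table. Rows were present for 7 of the 8 congener comparisons and for that direct comparison.

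The number of genes behind each adjustment was recovered as the whole number that turns the ratio of unadjusted to adjusted p into whole ranks (tolerance 0.0001). It was 11313 for each comparison with rows except PCB153 at 96 h, for which it was 10874. The highest whole rank gives a lower bound of the genes with an adjusted p under 0.05 at any fold change, which was 1158 for PCB180 and 386 for PCB153 at 96 h. On simulated p-values of 11000 genes, with effects and standard errors drawn from the rows of all comparisons, the method returned 11000 genes and 525 of 525 genes past the threshold.

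Since the tables hold only listed genes with no values per sample, no new test of single genes was made, and the authors' log2 fold changes, standard errors and adjusted p are given as deposited. The comparisons follow the plan made before the data were examined: genes counted per direction, overlaps and sign agreement between congeners and hours, differences of log2 fold changes between congeners, direction of functional lists, and annotated against unannotated genes. A difference between congeners was tested with a two-sided normal test, taking a correlation of 0.5 between comparisons that share a control, with 95% intervals and Benjamini-Hochberg adjustment within each pair. An adjustment over all pairs together was added after the values were seen. The overlap expected from shared controls alone came from 200 simulated pairs of comparisons with the same correlation and the observed list lengths. These simulated overlaps use the correlation of 0.5 alone, independent genes and no fold threshold, so they are an approximate reference. The 28 functional lists were defined by words in the annotation before the data were examined, and 4 of them matched no listed gene. Each list with at least 5 listed members was tested for direction against the other listed annotated genes of the comparison by a two-sided Fisher's exact test. A count adjusted over the list alone was not made, because list members past no threshold were not among the rows used here. In simulations modelled on the 620 annotated PCB180 genes, this test called 6.0% of random lists of 12 genes and 95.5% of lists of 20 genes planted with a rising majority, at an unadjusted p under 0.05. Most real lists had fewer than 20 members and were judged by an adjusted p, so this rate does not hold for them. Absolute log2 fold changes and log2 mean counts were compared with a permutation test of the difference of medians (100000 resamples). The tests of mean counts were not part of the plan. Neighbouring gene numbers were counted against 10000 random placements on the same contigs.

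The genes named were chosen by a rule set before the data were examined. They are the 6 annotated genes with the largest rise and the 6 with the largest fall per comparison, up to 4 members per list by absolute log2 fold change, the 10 annotated genes in the most comparisons, and at most 2 unannotated genes per direction. Genes named in the closing section as chosen after their values were seen stand outside this rule. Alternatives were an adjusted p under 0.01 or 0.001, an absolute log2 fold change of at least 1 or 2, leaving out the lowest 25% of genes by mean normalized count (77.5 or less), annotated genes only, list membership by the first annotation or by a single list, and, chosen after seeing the data, a correlation computed from 4 control libraries and lists freed of accidental word matches. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9.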

Results

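The mycelium of Cladosporium europaeum strain F32, a filamentous fungus from soil with a history of pollution by polychlorinated biphenyls (PCB), was grown in liquid medium with 5 g/L glucose and either no PCB or 6 mg/L of a single congener. The congeners differ in the number and position of their chlorine atoms: PCB52 is a tetrachlorobiphenyl, PCB101 a pentachlorobiphenyl, PCB153 a hexachlorobiphenyl and PCB180 a heptachlorobiphenyl. Polyadenylated RNA was sequenced after 24 h and 96 h of growth, in 50 samples that form 10 groups of 5 replicates, which are 4 congeners and a control at each of 2 times. The values analysed here are the authors' own comparisons of each congener with the control of the same hour, limited to the genes they listed as changed. These hold 1102 gene and comparison combinations over 920 genes, of which 705 carry an annotation. Each congener comparison listed genes with an adjusted p under 0.05 and an absolute log2 fold change of at least 1, and "rose" and "fell" below refer to genes listed in this way. A gene that is not listed passed at most 1 of these criteria, which does not show that it was unchanged. Library depth is unknown, since totals per sample were not used here, and the mean normalized count of the listed genes ran from 10.2 to 119992 with a median of 302 in the authors' deposited table. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples.

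The first question the design poses is which genes responded to each congener after 24 h. Few genes were listed, 1 for PCB52, 6 for PCB153 and 2 for PCB180, and no gene was shared between these congeners. The rows used here hold no gene for PCB101 at 24 h, and they do not show whether no gene passed or the comparison was not made. Under PCB52, a transporter of the major facilitator superfamily (ptg000021l.30), a family that moves small molecules across membranes, rose 118-fold, a log2 fold change of 6.88 ± 0.97 (standard error) at an adjusted p of 1.5e-08 in the authors' deposited table. Under PCB180, a Zn(2)-C6 transcription factor (ptg000011l.9), of a family restricted to fungi, rose by a log2 fold change of 4.98 ± 0.84 and a methyltransferase domain protein (ptg000003l.388) by 4.54 ± 1.0, per the authors' deposited table. The methyltransferase domain protein had a mean normalized count of only 13.5, near the lowest of the listed genes. Under PCB153, a reverse transcriptase (ptg000027l.84) rose by 2.08 ± 0.47, a protein with a CBM1 carbohydrate-binding domain (ptg000021l.603) by 1.94 ± 0.46 and dihydrofolate reductase (ptg000016l.182), which makes tetrahydrofolate, by 1.57 ± 0.35 in the authors' deposited table. A probable beta-glucosidase G (ptg000003l.425) fell by 2.14 ± 0.45 on the log2 scale and a glutathione synthetase ATP-binding domain-like protein (ptg000019l.561) fell by 1.09 ± 0.23 under PCB153 in the authors' deposited table. At this hour no fixed functional list had the 5 listed members its test needed. Of the 6 genes for PCB153, 0 had an adjusted p under 0.01.

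**Figure D1:**
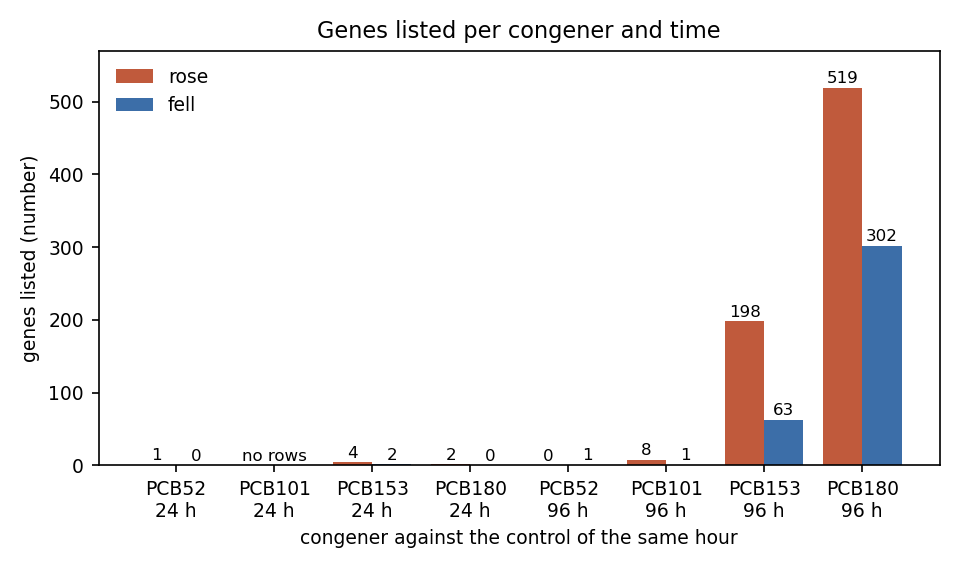
Number of genes listed per comparison of a congener with the control of the same hour (horizontal axis), with the number that rose and the number that fell as separate bars on a vertical axis that starts at 0. PCB180 at 96 h had 519 genes that rose and 302 that fell, PCB153 at 96 h had 198 and 63, and each other comparison with rows had 9 genes or fewer, while PCB101 at 24 h has no rows.

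At 96 h the numbers ran from 1 gene for PCB52 and 9 for PCB101 to 261 for PCB153 and 821 for PCB180. The 8 genes that rose under PCB101 included enzymes that act on aromatic rings. An intradiol ring-cleavage dioxygenase (ptg000021l.252), an enzyme type that opens catechol rings between the hydroxyl groups, rose by a log2 fold change of 3.67 ± 0.71 and phenol 2-monooxygenase (ptg000007l.259), which turns phenol into catechol, by 2.44 ± 0.50 in the authors' deposited table. A further intradiol dioxygenase (ptg000008l.232) rose by 1.22 ± 0.30, and FAD-binding proteins rose by 2.16 ± 0.51 (ptg000015l.287) and 1.35 ± 0.24 (ptg000032l.13), per the authors' deposited table. The remaining PCB101 genes that rose were a protein kinase (ptg000027l.189, 1.41 ± 0.34), a Zn(2)-C6 transcription factor (ptg000015l.431, 1.41 ± 0.26) and a major facilitator transporter (ptg000017l.105, 1.17 ± 0.23), with log2 fold changes from the authors' deposited table. A protein with an RRM domain (ptg000003l.539), a domain that binds RNA, was listed for all 4 congeners at 96 h. Its log2 fold change in the authors' deposited table was -1.1 ± 0.22 for PCB52, where it was the only gene, -1.14 ± 0.22 for PCB101, -1.24 ± 0.22 for PCB153 and -1.86 ± 0.23 for PCB180. These 4 comparisons share the 96 h control, so the values are not independent of each other. The adjusted p of the PCB101 genes lay between 0.000348 and 0.0474 in the authors' deposited table, and 5 of the 8 that rose were under 0.01.

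Under PCB153 at 96 h, 198 genes rose and 63 fell. The largest rises among annotated genes were in catabolic 3-dehydroquinase (ptg000008l.233), an enzyme of quinate breakdown, at a log2 fold change of 4.66 ± 0.78 and in the dioxygenase ptg000021l.252 at 4.43 ± 0.71, per the authors' deposited table. Phenol 2-monooxygenase (ptg000007l.259) followed at 3.49 ± 0.50, an F-box protein (ptg000002l.449) at 3.13 ± 0.65, a HIG1 domain protein (ptg000018l.327) at 3.08 ± 0.61 and a protein annotated both as an AGC/AKT kinase and as a C2H2 zinc finger (ptg000021l.85) at 2.84 ± 0.65 in the authors' deposited table. Falls were smaller, with an O-methyltransferase (ptg000005l.141) at -1.63 ± 0.42, an NmrA-like protein (ptg000010l.706) at -1.60 ± 0.42, a PRISE-like Rossmann-fold protein (ptg000012l.341) at -1.56 ± 0.37 and an FMN-linked oxidoreductase (ptg000016l.690) at -1.54 ± 0.37 in the authors' deposited table. A CASTOR ACT domain protein (ptg000021l.435) and an alcohol oxidase (ptg000015l.169) fell by 1.52 ± 0.45 and 1.45 ± 0.42 on the log2 scale, per the authors' deposited table. With an absolute log2 fold change of at least 2, 52 genes that rose and 0 that fell were left.

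Several of the functional lists fixed beforehand had members among the PCB153 genes at 96 h. Of the cytochrome P450 monooxygenases, 3 rose and 1 fell; benzoate 4-monooxygenase (ptg000027l.308), which hydroxylates benzoate, rose by a log2 fold change of 2.11 ± 0.27 at an adjusted p of 9.03e-11, the smallest for PCB153 in the authors' deposited table. A cytochrome P450 (ptg000007l.258) whose gene number directly precedes that of phenol 2-monooxygenase rose by 2.01 ± 0.39, and the gene number of the dioxygenase ptg000008l.232, at 1.48 ± 0.30, directly precedes that of the 3-dehydroquinase, by the authors' deposited table. Both listed dioxygenases rose, and so did both listed members of the flavin monooxygenase list. These members were phenol 2-monooxygenase and a protein annotated only by an FAD-binding domain, which does not name a monooxygenase. A protein with a dihydroxypyridine monooxygenase substrate binding domain is not in the flavin monooxygenase list. It fell under PCB153, at -1.03 in the authors' deposited table. All 8 listed members of the ribosome and translation list rose, with large subunit protein bL33m (ptg000021l.537) at 2.19 ± 0.60, mS33 (ptg000010l.315) at 1.90 ± 0.52 and uS19 (ptg000003l.671) at 1.77 ± 0.46 in the authors' deposited table. All 4 listed members of the mitochondrial respiration list rose, among them cytochrome c (ptg000005l.402), the electron carrier between complexes III and IV, at 2.17 ± 0.51 and the cytochrome c oxidase assembly factor COX23 (ptg000015l.37) at 1.76 ± 0.48 in the authors' deposited table. Peptidases went mostly the other way, with 1 that rose and 4 that fell, including a carboxypeptidase (ptg000005l.620) at -1.23 ± 0.36 in the authors' deposited table. A glutathione hydrolase is among the 4, and without it 3 fell, which is too few members for the test. Among transcription factors 11 rose and 3 fell, and a C2H2 protein (ptg000002l.310) rose by 2.46 ± 0.44 in the authors' deposited table. The split was 5 to 4 for major facilitator transporters, 4 to 0 for lipid and sterol metabolism, 2 to 1 both for conjugating transferases and for dehydrogenases and reductases, and 1 to 1 both for heat shock proteins and chaperones and for glycoside hydrolases. Without a chaperone of proteasome assembly, the heat shock and chaperone split was 1 to 0. Single listed members rose for epoxide hydrolases (ptg000010l.624, 1.5 ± 0.32) and amino acid transport (ptg000005l.832, 1.1 ± 0.33), and fell for glutathione S-transferases (ptg000019l.530, -1.07 ± 0.25) and antioxidant proteins (a thioredoxin, ptg000002l.457, -1.01 ± 0.28), by the authors' deposited table. The cell cycle and DNA list had 1 member that fell. A two-sided Fisher's exact test against the other listed annotated genes set the direction apart for 0 of the 4 lists with at least 5 members. Peptidases had an unadjusted p of 0.0175 and a Benjamini-Hochberg adjusted p of 0.0701, ribosome and translation 0.113 and 0.227, major facilitator transporters 0.246 and 0.328, and transcription factors 1 for both. All 8 listed ribosome and translation members rose, the most extreme rise possible, so the test could not call a rising list of that size.

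PCB180 at 96 h had the longest list, with 519 genes that rose and 302 that fell. The kinase and zinc finger protein ptg000021l.85 had the largest rise of an annotated gene, a log2 fold change of 3.84 ± 0.69, before catabolic 3-dehydroquinase (ptg000008l.233) at 3.65 ± 0.83, in the authors' deposited table. A secreted protein (ptg000015l.370) rose by 3.46 ± 0.92, a DUF4396 protein (ptg000027l.78) by 3.42 ± 1.07, endo-polygalacturonase (ptg000015l.518), which cuts pectin, by 3.18 ± 0.67 and aspartate aminotransferase (ptg000027l.191) by 3.02 ± 0.49, per the authors' deposited table. The largest falls of annotated genes were in a metallo-hydrolase or oxidoreductase (ptg000015l.152, -2.47 ± 0.44), stress response protein ish1 (ptg000008l.560, -2.19 ± 0.51) and a cell surface protein (ptg000003l.345, -2.19 ± 0.31), as log2 fold changes of the authors' deposited table. They were followed by a DUF1771 protein (ptg000021l.326, -2.17 ± 0.59), a cortex domain protein (ptg000016l.178, -2.16 ± 0.50) and a DUF221 protein (ptg000015l.228, -2.11 ± 0.34) in the authors' deposited table. Genes that rose had a median mean normalized count of 143 and genes that fell one of 527 (permutation test over genes, two-sided p = 1e-05, the smallest the resamples can give), whereas for PCB153 the medians were 421 and 381 (p = 0.641). These tests of counts were not part of the plan.

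The fixed lists were better filled for PCB180. Major facilitator transporters split 16 to 4 in favour of rises, with ptg000009l.769 at a log2 fold change of 1.88 ± 0.52, ptg000017l.544 at 1.86 ± 0.64 and ptg000018l.409 at 1.59 ± 0.29 in the authors' deposited table. The ribosome and translation list split 10 to 1, with bL33m (ptg000021l.537) at 2.48 ± 0.63 and uS19 (ptg000003l.671) at 1.94 ± 0.48 in the authors' deposited table. Of 5 listed glutathione S-transferases, which attach glutathione to electrophiles, 4 fell, with ptg000019l.530 at -1.76 ± 0.26, ptg000009l.39 at -1.47 ± 0.31 and GstA (ptg000010l.367) at -1.41 ± 0.40, while ptg000018l.403 rose by 2.29 ± 0.61, in the authors' deposited table. Cytochrome P450 monooxygenases split 3 to 2, among them ptg000010l.658 at 2.18 ± 0.59, benzoate 4-monooxygenase (ptg000027l.308) at 1.43 ± 0.29 and ptg000018l.79 at -2.02 ± 0.48 in the authors' deposited table. All 4 listed members of the flavin monooxygenase list rose, with phenol 2-monooxygenase (ptg000007l.259) at 2.33 ± 0.53 in the authors' deposited table. Other members of this list are annotated only by an FAD-binding domain, which does not name a monooxygenase. A protein with a dihydroxypyridine monooxygenase substrate binding domain is not in this list. It fell under PCB180, at -1.48 in the authors' deposited table. Both listed dioxygenases rose, with ptg000021l.252 at 2.14 ± 0.75 and a sulfonate dioxygenase (ptg000010l.24) at 1.58 ± 0.41, by the authors' deposited table. Both listed epoxide hydrolases rose, ptg000010l.624 by 2.31 ± 0.34 and ptg000021l.294 by 1.42 ± 0.47 in the authors' deposited table. Dehydrogenases and reductases split 11 to 9, and a protein annotated as the dehydrogenase LinX (ptg000021l.590), named for a step of bacterial lindane breakdown, rose by 1.77 ± 0.53 in the authors' deposited table. Conjugating transferases split 5 to 3, with an N-acetyltransferase domain protein (ptg000009l.300) at 2.85 ± 0.75 and a glycosyltransferase (ptg000005l.85) at -1.94 ± 0.42 in the authors' deposited table.

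Cell surface and secreted proteins moved in both directions under PCB180. Glycoside hydrolases and related enzymes split 10 to 6, a count that includes aminoglycoside phosphotransferases matched by their name alone (ptg000021l.539, 2.17 ± 0.76, and ptg000008l.627, 2.08 ± 0.62, by the authors' deposited table). With these removed, a choice made after seeing the data, 6 rose and 6 fell. In the cell wall list 2 rose and 3 fell, with chitinase (ptg000019l.437) at -1.59 ± 0.45 and an exo-1,3-beta-glucanase (ptg000007l.368) at 1.59 ± 0.52 in the authors' deposited table. Cerato-platanin (ptg000009l.254), a small secreted fungal protein, fell by 1.78 ± 0.50 and tyrosinase (ptg000021l.131), an enzyme of melanin formation, rose by 1.30 ± 0.33 on the log2 scale in the authors' deposited table. Peptidases split 7 to 8, with peptidase A1 proteins on both sides (ptg000015l.84, 2.18 ± 0.58, and ptg000006l.45, -2.06 ± 0.56, in the authors' deposited table). The lipid and sterol list split 4 to 6, with phosphoinositide phospholipase C (ptg000008l.73) at -1.90 ± 0.53 in the authors' deposited table. Central carbon genes split 5 to 3, and both pyruvate decarboxylases, which open the route from pyruvate to ethanol, rose, ptg000009l.403 by 1.66 ± 0.51 and ptg000021l.20 by 1.61 ± 0.44 in the authors' deposited table. The cell cycle and DNA list split 5 to 2, with histone H4 (ptg000007l.243) at 1.97 ± 0.66 and DNA polymerase epsilon subunit B (ptg000010l.96) at 1.65 ± 0.30 in the authors' deposited table. Without a dopachrome isomerase matched by its name alone, the central carbon split was 4 to 3. Heat shock proteins and chaperones split 1 to 3, or 1 to 1 without chaperones of chitin synthase export and proteasome assembly. Transcription factors split 11 to 13, and ABC transporters and antioxidant proteins 1 to 1 each, with a catalase (ptg000019l.156) at 1.77 ± 0.56 and the thioredoxin ptg000002l.457 at -1.40 ± 0.30 in the authors' deposited table. Both listed respiration genes rose, as did the single listed secondary metabolism gene (ptg000015l.603), which is also annotated as ribosomal protein S3, at 2.08 ± 0.62 in the authors' deposited table. By the same two-sided Fisher's exact test the direction was set apart for 0 of the 13 lists with at least 5 members. The lowest unadjusted p were 0.0284 for ribosome and translation and 0.0393 for major facilitator transporters, each with a Benjamini-Hochberg adjusted p of 0.256, and glutathione S-transferases had 0.170 and 0.738. The words for laccases and peroxidases, sugar transporters, iron and metal handling and conidiation matched no listed gene of any comparison. This does not show that such genes were absent, since genes with no or only a general annotation could not match.

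The structurally related congeners were compared at the matched dose and hour. Of the 261 PCB153 genes 171 were also listed for PCB180, 122 that rose and 49 that fell under both, and 171 of 171 had the same direction. Independent lists of these lengths would share 9.45 rising and 1.75 falling genes, and simulated comparisons with no effect but a shared control shared 77.2 on average and 96 at most in 200 draws, 99.9% of them with the same direction. All 9 PCB101 genes were listed for PCB153 and 7 of them for PCB180, against 2.65 and 4.7 on average with no effect and a shared control, and at most 7 and 8. The 7 are thus within what a shared control alone gave. The 1 PCB52 gene was also listed for PCB101, PCB153 and PCB180, against 0.08, 0.485 and 0.605 on average in such simulations, and at most 1 for each. The simulation drew genes independently and applied no fold threshold, so its maxima are not firm upper limits for the real lists. The control libraries could not be split here, so part of the other overlaps may come from the shared controls too. Over the 171 genes, the PCB180 log2 fold change minus that of PCB153 had a median of 0.01, and the 95% interval of the difference included 0 for 153 genes. This median pools genes that rose with genes that fell, so larger changes of opposite sign under PCB180 cancel in it. For the dioxygenase ptg000021l.252 the difference was -2.30 (95% interval -3.73 to -0.86), for phenol 2-monooxygenase (ptg000007l.259) -1.17 (-2.18 to -0.15) and for benzoate 4-monooxygenase (ptg000027l.308) -0.68 (-1.23 to -0.14), each computed from the authors' deposited table. Of the differences with an unadjusted p under 0.05, only these were changes smaller in size under PCB180, and all others were larger in size. The larger ones included aspartate aminotransferase (ptg000027l.191) at 1.04 (0.10 to 1.98) and an epoxide hydrolase (ptg000010l.624) at 0.81 (0.16 to 1.45), likewise computed from the authors' deposited table. Among genes that fell, the unannotated ptg000018l.213 differed by -1.24 (-1.99 to -0.49), computed in the same way. Of the 171 differences 18 had an unadjusted p under 0.05, where 8.55 would by chance, and 0 passed a Benjamini-Hochberg adjustment, the smallest adjusted p being 0.146. The 171 genes were selected by being listed in both comparisons, whereas the chance number holds for unselected genes. Genes with a strong difference can be missing from them. The authors' direct comparison of PCB180 with PCB153 at 96 h listed 1 gene, L-galactonate dehydratase (ptg000017l.227), at a log2 fold change of 0.86 ± 0.16 and an adjusted p of 0.000468, and PCB180 against control gave 1.05 ± 0.17 for it, in the authors' deposited table.

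**Figure D2:**
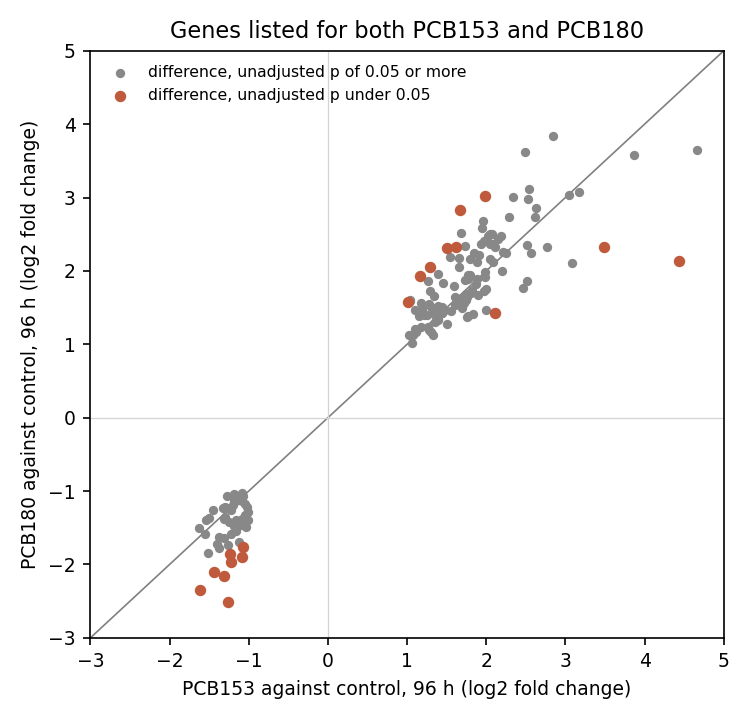
Log2 fold change against control at 96 h for PCB153 (horizontal axis) and PCB180 (vertical axis), for the 171 genes listed for both, with the line of equal values. All points lie in the quadrants of equal direction, and the 18 coloured genes have an unadjusted p under 0.05 for the difference, of which 0 passed the adjustment.

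PCB101 could be set against the other congeners only over the genes it shares with them. Over its 7 genes shared with PCB180, the PCB180 value was lower by 0.72 for the RRM protein ptg000003l.539 (difference -0.72, 95% interval -1.16 to -0.28), and higher for the transcription factor ptg000015l.431 (0.80, 0.28 to 1.32) and the kinase ptg000027l.189 (0.91, 0.23 to 1.59), computed from the authors' deposited table. These 3 had Benjamini-Hochberg adjusted p of 0.00925, 0.00963 and 0.0209 over the 7 genes. The dioxygenase ptg000021l.252 had the largest difference in size, lower under PCB180 (-1.53, -2.97 to -0.10), with an adjusted p of 0.0637, computed from the authors' deposited table. When the 190 differences over all pairs of congeners were adjusted together, 0 passed. Limited to genes with an adjusted p under 0.01 in both comparisons, 2 passed, namely the RRM protein between PCB180 and each of PCB101 and PCB52. Between PCB153 and PCB101 the differences of phenol 2-monooxygenase (ptg000007l.259) at 1.05 (0.07 to 2.04) and of the dioxygenase ptg000021l.252 at 0.76 (-0.63 to 2.16) had an adjusted p of 0.165 or more over 9 genes, computed from the authors' deposited table. Genes listed for 1 congener and not for another were not tested for a difference here.

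**Figure D3:**
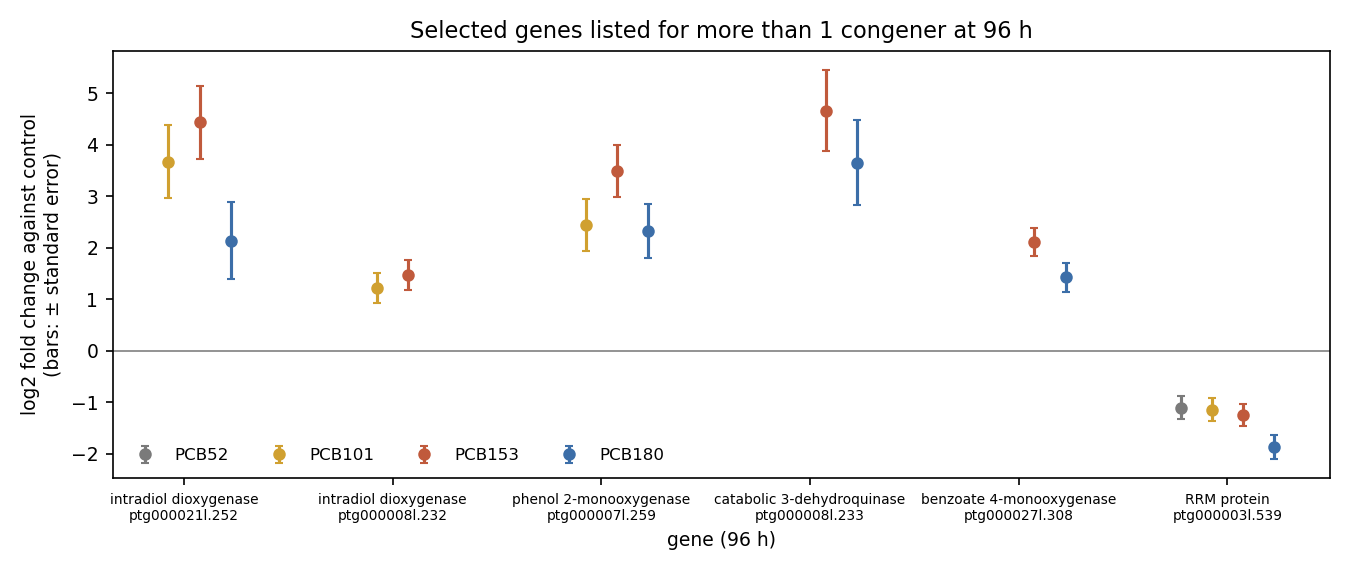
Log2 fold change against control at 96 h (vertical axis; points, with the authors' standard error as bars) for 6 genes listed for more than 1 congener (horizontal axis), coloured by congener; a missing point means that the gene was not listed for that congener. The dioxygenase ptg000021l.252 stands at 3.67 for PCB101, 4.43 for PCB153 and 2.14 for PCB180 in the authors' deposited table, and the RRM protein is below 0 for all 4 congeners.

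The change of the response between the hours was the remaining question of the design. For PCB52, PCB153 and PCB180, 0 genes were listed at both 24 h and 96 h, and PCB101 has no rows at 24 h, so no sign test over shared genes could be made. The transporter ptg000021l.30, at 6.88 under PCB52 after 24 h, and the transcription factor ptg000011l.9, at 4.98 under PCB180 after 24 h, were not listed for any congener at 96 h in the authors' deposited table. Conversely the 3-dehydroquinase, the dioxygenases and phenol 2-monooxygenase were listed at 96 h only. Whether the fold changes differ between the hours was not tested, and the controls of 96 h against 24 h were not analysed here.

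Genes with no annotation made up 67 of the 261 PCB153 genes and 201 of the 821 PCB180 genes at 96 h. Under PCB180, 82.1% of unannotated and 57.1% of annotated genes rose (165 of 201 and 354 of 620; two-sided Fisher's exact test p = 5.39e-11), and under PCB153 82.1% and 73.7% (p = 0.188). The unannotated genes with the largest rises were ptg000021l.664, at a log2 fold change of 3.87 ± 0.93 under PCB153, and ptg000016l.447, at 3.62 ± 0.79 under PCB180, while ptg000018l.480 at -2.63 ± 0.72 and ptg000018l.213 at -2.51 ± 0.39 under PCB180 had the largest falls, in the authors' deposited table. The mean normalized counts of the rising ptg000021l.664 and ptg000016l.447 were only 10.6 and 13.8, near the lowest of all listed genes (10.2). The median absolute log2 fold change of unannotated genes was 1.70 against 1.40 for annotated genes under PCB180 (permutation test, two-sided p = 1e-05, the smallest the resamples can give) and 1.68 against 1.44 under PCB153 (p = 0.0135). Their median mean normalized count was lower, at 65.7 against 398 under PCB180 and 88.5 against 576 under PCB153. Under PCB180 the genes that rose also had lower counts than those that fell. The Fisher's exact test does not take count level into account, so annotation and count level are not separated by it. These tests run across genes, which are not independent replicates. With an absolute log2 fold change of at least 2, the difference in the rising share under PCB180 was 2.73 percentage points (Fisher's exact test p = 0.786).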

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

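The tests of differences between congeners were planned, and the adjustment over all pairs was chosen after the values were seen. L-galactonate dehydratase (ptg000017l.227), an enzyme named for a step of galacturonate breakdown, differed between congeners in a direct test: its log2 fold change of PCB180 over PCB153 at 96 h was 0.86 with an adjusted p of 0.000468 in the authors' deposited table. It was listed for PCB180 against control and not for PCB153.

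The RRM domain protein ptg000003l.539 fell further under PCB180 than under PCB52 (difference -0.76, adjusted p 0.000699 for the 1 shared gene) and than under PCB101 (-0.72, adjusted p 0.00925 over 7 genes), computed from the authors' deposited table. The Zn(2)-C6 transcription factor ptg000015l.431 and the protein kinase ptg000027l.189 rose further under PCB180 than under PCB101, by 0.80 (adjusted p 0.00963) and 0.91 (adjusted p 0.0209) over the same 7 genes, computed from the authors' deposited table. Adjusted over all 190 differences, the p of these was 0.0812 for both differences of the RRM protein, 0.105 for the transcription factor and 0.170 for the kinase.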

How the results depend on the processing

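The alternatives here were planned, except the correlation from 4 control libraries, the adjustment over all pairs and the lists freed of accidental word matches, which were chosen after seeing the data. No paired analysis was possible because the tables used hold no values per sample. For the same reason another normalization or count filter, another pseudocount, leaving out replicates and a fit of only the groups compared were not run. Each stricter threshold removes genes by its construction. At an adjusted p under 0.01, PCB153 at 96 h had 75 genes that rose and 23 that fell, PCB180 225 and 159, and PCB101 5 that rose, while at 24 h PCB153 had 0 and 0 and PCB180 1 that rose. Under 0.001 these were 33 and 7 for PCB153, 67 and 63 for PCB180, 3 for PCB101, and 0 and 0 and 1 at 24 h, with 0 that fell for PCB52. At an absolute log2 fold change of at least 2, PCB153 at 96 h had 52 and 0, PCB180 129 and 15, PCB101 3 and 0, PCB52 0, and PCB153 at 24 h 1 and 1. Without the lowest 25% of genes by mean normalized count, PCB180 had 332 genes that rose and 274 that fell, and at 24 h PCB153 had 2 and 1 and PCB180 1. The share that rose under PCB180 went from 63.2% to 51.5% at an adjusted p under 0.001, to 54.8% without the lowest 25% by count and to 89.6% at a log2 fold change of at least 2. The direct comparison of PCB180 with PCB153 had 0 genes at a log2 fold change of at least 1 or 2. PCB153 and PCB180 shared 56 genes at an adjusted p under 0.01 and 30 at a log2 fold change of at least 2, where PCB101 shared 3 with PCB153 and 2 with PCB180, and PCB52 shared 0 with each. Of the shared genes of PCB153 and PCB180, the difference had an unadjusted p under 0.05 for 10 and 2 under these settings, and 0 passed the adjustment in each. Adjusted over all pairs, 2 differences passed among genes with an adjusted p under 0.01, both of the RRM protein (PCB180 against PCB52 and against PCB101), where fewer differences were tested. At a log2 fold change of at least 2 the excess of rising genes among unannotated PCB180 genes was 2.73 percentage points (Fisher's exact p = 0.786), and the excess of their median absolute log2 fold change under PCB153 was 0.18 (permutation p = 0.378), with fewer genes in each test. The number of lists set apart by direction was 0 at an adjusted p under 0.01, by the first annotation, with genes of a single list and without accidental matches. At an adjusted p under 0.01 the PCB180 split of dehydrogenases and reductases turned from 11 to 9 into 4 to 8, and that of transcription factors from 11 to 13 into 7 to 6. At a log2 fold change of at least 2 no list had the 5 members its test needs, and the other thresholds were not applied to lists. Of 147 gene values named by the rule, 92 had an adjusted p under 0.01. Depth per library is unknown and limits no value in a way that could be measured here.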

Other observations

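The tests named here were chosen after the values were seen, and so were the genes of the first 2 paragraphs, which are given as values and not as tested groups. Of 6 listed genes of purine breakdown, 5 rose under PCB153 and 2 under PCB180 at 96 h. Under PCB153 these included uricase (ptg000009l.79) at a log2 fold change of 2.37 ± 0.48, adenine deaminase (ptg000002l.379) at 2.11 ± 0.55, allantoicase (ptg000012l.230) at 1.83 ± 0.42 and 5-hydroxyisourate hydrolase (ptg000027l.529) at 1.54 ± 0.39 in the authors' deposited table. The decarboxylase of the same route (ptg000016l.128) stood at 1.74 ± 0.50 under PCB153 and 1.69 ± 0.52 under PCB180, and ureidoglycine aminohydrolase (ptg000017l.123), not listed for PCB153, at 1.38 ± 0.35 under PCB180, in the authors' deposited table. None of the 6 purine genes was listed in the authors' direct comparison of PCB180 with PCB153. The counts of 5 and 2 therefore do not show a difference between these congeners. Further genes whose annotations name the breakdown of aromatic compounds rose too. A carboxymuconolactone decarboxylase-like protein (ptg000015l.273) stood at 2.0 ± 0.39 under PCB153 and 1.47 ± 0.41 under PCB180 in the authors' deposited table. A carboxymuconate lactonizing enzyme (ptg000015l.409) stood at 1.25 ± 0.34 under PCB153 in the authors' deposited table. The protein with a dihydroxypyridine monooxygenase substrate binding domain fell, at -1.03 under PCB153 and -1.48 under PCB180 in the authors' deposited table. Of 10 listed genes annotated as mitochondrial or bacterial-type ribosomal proteins, 7 rose under PCB153 and 8 under PCB180, and 0 fell, where 198 of all 261 listed genes rose under PCB153 and 519 of 821 under PCB180. All 3 listed genes for diphthamide, a modified histidine of translation elongation factor 2, rose under PCB180, between 1.81 and 2.06 in the authors' deposited table.

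The 3 listed enzymes of branched-chain amino acid breakdown rose under PCB180 and were listed for no other congener, isovaleryl-CoA dehydrogenase (ptg000016l.134, 1.51 ± 0.35) and methylcrotonoyl-CoA carboxylase (ptg000016l.135, 1.80 ± 0.28) with adjacent gene numbers, and 2-oxoisovalerate dehydrogenase subunit alpha (ptg000021l.84, 1.36 ± 0.41), by the authors' deposited table. Under PCB180 519 of all 821 listed genes rose, which stands beside each group here. The authors' direct comparison of PCB180 with PCB153 listed 1 gene, L-galactonate dehydratase, which belongs to none of these groups. Being listed for PCB180 and not for PCB153 therefore does not show that a gene differed between these congeners. All 7 genes grouped here as feruloyl esterases and enzymes acting on pectin and related polymers rose under PCB180. They ran from 1.06 for feruloyl esterase C (ptg000015l.540) to 3.18 for endo-polygalacturonase (ptg000015l.518) in the authors' deposited table. A feruloyl esterase (ptg000012l.515) had 1.11 ± 0.22 in the authors' deposited table. The group leaves out an alpha-L-rhamnosidase domain protein, which fell under PCB180, at -1.18 in the authors' deposited table. The polygalacturonase is also in the glycoside hydrolase list, which split 10 to 6, or 6 to 6 without accidental matches. Of 10 rhodopsin domain proteins listed for any congener, 9 rose under PCB180 and 2 under PCB153, and 0 fell. Of 9 listed genes for heterokaryon incompatibility, HeLo and NACHT domains 6 rose and 2 fell under PCB180, and all 4 listed RNA polymerase subunits rose. Of 11 listed genes grouped as protein kinases by their annotation, 3 rose and 8 fell under PCB180. Of all 821 listed genes 302 fell, and no test was made. Among the 8 that fell were Aurora kinase (ptg000017l.33) at -1.37 ± 0.27 and cAMP-dependent protein kinase (ptg000017l.248) at -1.03 ± 0.22 in the authors' deposited table. Another of the 8 is annotated only by an AMP-activated protein kinase glycogen-binding domain (ptg000016l.236, -1.08 ± 0.33, in the authors' deposited table). This name does not show that the protein is a kinase. The largest of the 3 rises was in a protein also annotated as a C2H2 zinc finger. The counts can therefore include genes that are not kinases.

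The authors' standard errors at 96 h carry a pattern: over 171 genes the PCB153 value was a median 0.949 of the PCB180 value (range 0.922 to 0.968), computed from the authors' deposited table. If all 10 groups had entered the model with 5 libraries the ratio would be near 1, which the observed median argues against. With 4 control, 5 PCB153 and 4 PCB180 libraries the ratio would be 0.949 as well, and the direct comparison of PCB180 with PCB153 gave 0.947 of the PCB180 value for its 1 gene. A candidate explanation is therefore that 1 control and 1 PCB180 library at 96 h did not enter the authors' model. No biological explanation was tested for this pattern.

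Many genes were listed for PCB153 and PCB180 at 96 h and few for PCB52 and PCB101. Larger standard errors in the comparisons with few genes are argued against only for 7 genes, where the PCB101 standard errors were a median 0.949 of those for PCB180. These genes were selected by being listed for both, so genes with larger standard errors under PCB101 can be missing. For PCB52 the ratio rests on 1 gene (0.946). Deviating control libraries, shared by all 4 comparisons, cannot be told apart as a cause: among listed genes, 50 for PCB153 and 1 for PCB52 passed an absolute statistic of 4.44, but this recounts the pattern itself and leaves out genes below the fold threshold. A difference in handling between the groups of libraries stays open too. That the congener itself sets the number of responding genes may be true and is likewise open, as it was not tested.

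Genes that rose under PCB153 often had adjacent gene numbers on a contig, in 26 pairs against a mean of 3.72 and a maximum of 15 in 10000 random placements, so chance placement is argued against (permutation p = 1e-04, the smallest the placements can give). For PCB180 there were 39 such pairs among genes that rose against 24.2 (permutation p = 0.0026) and 17 among genes that fell against 7.87 (p = 0.0032), and for PCB153 genes that fell 2 pairs against 0.376 (p = 0.0565). All 14 of the 14 pairs annotated on both sides had different annotations, the criterion first set against a gene split into adjacent models. It was wrong, since different domains can belong to 1 protein and only 2 of the 14 pairs name no domain, so a split cannot be told apart. If reads of overlapping neighbours were counted for both, the more abundant member would tend to have the larger fold change, which held in 14 of 26 pairs (53.8%, exact 95% interval 33.4% to 73.4%), so this cannot be told apart from other explanations without gene coordinates. Shared regulation of neighbouring genes is a candidate explanation that was not tested. The median absolute difference of log2 fold changes was 0.69 within the 26 pairs and 0.48 over all pairs of these genes, and whether these differ was not tested.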
